A study of Mus musculus with 6 samples.

How the data were processed

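The series holds 6 single-cell RNA libraries of dermal collecting lymphatic vessels, taken with the surrounding tissue between the inguinal and axillary lymph nodes of C57BL/6 mice. Collecting lymphatic vessels are the muscular, valved vessels that pump lymph. Mice were 6 weeks (young), 12 months (middle-aged) or 18 months (aged) old, and each age has 1 library labelled male and 1 labelled female. Evans Blue dye was injected to make the vessels visible, and the tissue was digested with enzymes and freed of red cells before droplets were made. How many mice went into a library is not stated, so every p-value here measures only the spread between these 6 samples. Per the labels the 18-month mice came from another supplier than the younger ones, so supplier and age vary together.

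Per the file headers the deposited values are raw UMI counts (unique molecular identifiers, 1 per captured transcript) per gene and droplet barcode, made by the authors with Cell Ranger 3.0.2 against the mm10 build. No cell calling or normalization had been applied to them. The labels name a 10x 3′ kit of v2 chemistry, while the 6794880 barcodes listed per library are the number of a later kit. The submitters also name Seurat, without a version or filters, and their cell annotation was not used here. Of 31053 gene IDs in the count matrices, 31011 were found in GENCODE M21 (GRCm38), from which coordinates were taken. Genes sharing a symbol (71 IDs) were summed, which left 31017 symbols.

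Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Scrublet, with 6% expected doublets, marked 590 of 24488 barcodes (2.41%), from 0.100% in the labelled middle-aged female library to 3.51% in the young male one, and these were removed. The 23898 cells left were clustered without batch correction on 30 principal components of 2000 variable genes (15 neighbours, Leiden resolution 1) with scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0 and igraph 0.11.9 under Python 3.11.15, with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Of 27 clusters, 23 were named from 161 markers in 21 lists, which gave 14 classes. The 4 others, with too few markers or leading genes of more than 1 class, stayed unnamed. The class called muscle is the cluster led by smooth muscle markers, and it may hold lymphatic and blood vessel muscle together. Pericyte markers named no cluster, so pericytes may lie in this class or in an unnamed one.

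UMI counts were summed per library and class, since cells are not replicates. Sums of at least 20 cells were compared with edgeR 4.0.16 under R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test) in a model of age and labelled sex. Calls have a Benjamini-Hochberg adjusted p under 0.05. Values are log2 fold changes with their standard error (SE), CPM (UMIs scaled to a common total of all genes in the sum), or normalised CPM, which use the TMM factors. The comparisons were aged against young in muscle, lymphatic endothelium, fibroblasts and macrophages, both middle-age contrasts in muscle, and labelled female against labelled male in the same 4 classes. Ion channel and calcium handling genes were compared between muscle and the mean of the other classes with library as a block. Class shares were compared as cell numbers with the library total as offset. Aged female muscle (3 cells) and lymphatic endothelium (4 cells) fell below the minimum, so in both classes the aged side is the aged male library, with 5 sums and 1 residual degree of freedom.

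There were 25 gene lists. They covered the contractile apparatus, ion channels, inflammatory cytokines, interferon response, antigen presentation by MHC class I and II, collagens and matrix, senescence, dissociation and immediate early genes, oxidative phosphorylation, antioxidant defence, complement, endothelial junctions, lymphatic identity, resident macrophage genes and cell cycle. The other 9 held markers of fibroblasts, macrophages, smooth muscle, endothelium, lymphocytes, erythrocytes, skeletal muscle, epithelium and adipocytes. Lists with at least 3 tested members went through camera of limma 3.58.1 with a correlation of 0.01 on log-CPM (prior count 2), with an estimated correlation beside it, and through fry. Members were counted by the gene tests over all genes and adjusted over the list alone.

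Named genes followed a rule. For each class and contrast it took up to 6 genes per direction with the largest fold among calls of at least 30 CPM that moved the same way in both sexes (for sex, at every age). With fewer than 3 calls it took the 3 of smallest p, stated as not past the threshold. It added up to 4 members per list in muscle and 2 elsewhere by smallest p, and genes fixed for each class and for the sex check. Hemoglobin, immunoglobulin, mitochondrial and predicted genes were not taken for their fold. In muscle and lymphatic endothelium only the male libraries could show the direction for contrasts with the aged sum. For sex in these classes only the young and middle-aged pairs could show it. Of the genes the rule took, 2 are not reported here, and their values were left out of the tables of alternatives.

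The comparisons, tests, lists, markers and naming rule, and most alternatives, were set before the data were examined. These were DESeq2 1.42.0, RLE factors, no count filter, a model without the covariate, other cell filters (1000 genes; 5% mitochondrial UMIs; 200 genes with 20%), doublets kept, resolution 2, clustering without the channel genes, sums thinned to 1 depth, subtraction of free RNA (its profile from barcodes of at most 100 UMIs), other share denominators, and each library left out in turn. Added after seeing the data were the middle-aged pair left out, its sex labels exchanged in the covariate, sums of any cell number, an unnamed cluster put back into the fibroblasts, muscle cells and lymphatic endothelial cells rich in fibroblast markers left out (at least 15 cells per sum), and the change beyond that of fibroblasts or macrophages of the same libraries. The rule that names clusters and the free-RNA estimate were also settled after a first look at clusters and counts. Summing shared symbols, done after a first clustering had been seen, changed the clusters.

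Depth ran from 9616652 to 28921825 UMIs per library, and from 55620 to 232808 UMIs per muscle sum fitted. Intervals are exact 95% ones (Clopper-Pearson for shares, Poisson for UMIs) and cover counting error only; a count of 0 is given the limit of 3 counts for shares, and list medians were also taken with members at 0 in a whole age group set to 3 counts over that group. Pairs of libraries of 1 age were checked for copies and were not copies, with at most 9 shared cell barcodes.

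Each main test was tested on simulated data of the same design, after the first fits had been seen, with 200 changed genes per comparison. Of genes changed 8-fold it recovered 56.1% in muscle, 60.6% in lymphatic endothelium, 65.2% in fibroblasts and 87.9% in macrophages for aged against young. Of genes changed 2-fold it recovered 2.99%, 0%, 1.49% and 1.49%. Unchanged genes were 7.94%, 0%, 15.0% and 6.12% of the calls. In simulated lists camera with its fixed correlation called the moved list in each class, and 2 unmoved lists in muscle and 0 in the others, while with an estimated correlation it called 0 of 4 moved lists and fry 1 of 4. A neutrophil share changed 16-fold was called in 5.5% of 200 draws, and one changed 64-fold in 13.5%. The starting share was the mean over libraries and the library totals were held. The 64-fold setting therefore exceeds all cells of a library, a share that cannot occur. Simulated genes were drawn independently of each other, and for the age comparisons without a sex effect. Correlated genes and wrong sex labels were therefore not covered. The comparisons beyond fibroblasts or macrophages were not simulated.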

Results

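Collecting lymphatic vessels carry lymph by contractions of the muscle in their wall, and the libraries were labelled by age and sex, so the comparisons ask what differs with age and with sex in the muscle, the lymphatic endothelium and the cells around them. There were 6 libraries, 1 labelled male and 1 labelled female at each of 3 ages. They held 28921825 UMIs (young male), 18244101 (young female), 23208824 (labelled middle-aged male), 9616652 (labelled middle-aged female), 15620814 (aged male) and 15283182 (aged female). In the same order 7939, 4434, 6185, 998, 2931 and 1411 cells were kept, with median depths of 2619.5, 2829.5, 2536, 7508, 4188 and 3826.5 UMIs. The unnamed clusters held 17.4%, 8.64%, 12.5%, 8.92%, 15.5% and 17.5% of the cells.

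Muscle was a rare class, with 86, 23, 49, 33, 33 and 3 cells per library in that order, and so was lymphatic endothelium, with 25, 23, 21, 91, 96 and 4 cells. Fibroblasts, which make the collagen matrix around the vessel, gave 3284, 1842, 3000, 409, 1436 and 406 cells. Macrophages, which take up debris and digest matrix in the vessel surroundings, gave 1168, 819, 1488, 87, 548 and 276. UMIs per sum fitted ran from 76706 to 904785 in lymphatic endothelium, from 2354798 to 11417014 in fibroblasts and from 618468 to 2987649 in macrophages.

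Xist is the RNA that coats the inactive X chromosome and is made in cells with more than 1 X, while Ddx3y, Eif2s3y, Kdm5d and Uty lie on the Y chromosome. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254) was counted at 1358 CPM in young female and 883 CPM in aged female, and at 0.0833 and 0.0794 CPM in young and aged male. The 4 Y-linked genes together, led by Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629), were counted at 172 and 257 CPM in young and aged male and at 0.210 and 0.0877 CPM in young and aged female. Both middle-aged libraries went against their labels. The library labelled middle-aged male had 1406 CPM of Xist and 0.111 CPM of Y-linked genes, and the library labelled middle-aged female had 0.255 and 265 CPM. Xist was seen in 87.3% and 0.200% of the cells of these libraries, and Ddx3y in 0% and 57.5%. The labels were kept as given in every fit apart from the alternative that exchanges those of the middle-aged pair. Each direction drawn from a fit with the labels of that pair as given rests partly on labels that these genes contradict.

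**Figure D1:**
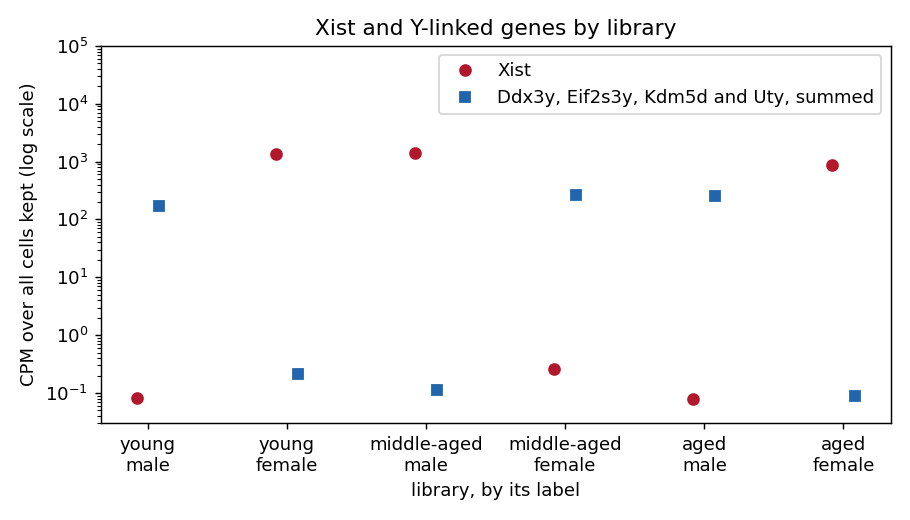
Xist and summed Y-linked counts (CPM of all cells, log axis) in each of the 6 libraries, 1 point per library and gene group. The library labelled middle-aged male has the Xist level of the young and aged female libraries, and the library labelled middle-aged female has the Y-linked level of the male ones.

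Contraction of lymphatic muscle is paced by ion channels and by calcium released from the sarcoplasmic reticulum. Phospholamban (Pln), the brake of the calcium pump of the reticulum, was the most muscle-restricted gene of the list of ion channel and calcium handling genes. Voltage-gated sodium (Scn3a) and calcium (Cacna1c) channels, the pacemaker chloride channel Ano1 and the connexins Gjc1 and Gja4 were also higher in muscle than in the mean of the other classes. The mechanosensor Piezo1 and the connexin Gja1 were instead highest in lymphatic endothelium. Of 44 listed genes 39 were measured, and 31 were higher and 4 lower in muscle than in the mean of 13 other classes, the same counts as adjusted over the list alone. Muscle had the highest mean of any class for 23 of them. Muscle values are means over 5 libraries with SD.

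Pln (ENSMUSG00000038583, chromosome 10, 53337667 to 53345987) had 234 ± 56.9 CPM (SD, n = 5) in muscle and 1.10 CPM in cycling cells, the next class. Its log2 difference from the mean of the other classes was 9.98 ± 0.39 (SE, edgeR adjusted p = 1.8e-21). Each log2 value in this paragraph is against that mean, taken on the log scale, and not against the class whose CPM is given. Where the other classes lie near 0, as for Pln, its size rests on those low counts. Scn3a (ENSMUSG00000057182, chromosome 2, 65457118 to 65567627) had 149 ± 53.1 CPM against 6.03 CPM in lymphatic endothelium (log2 8.97). Cacna1c (ENSMUSG00000051331, chromosome 6, 118587240 to 119196418) had 92.1 ± 22.8 CPM against 14.6 CPM in blood endothelium (log2 8.42), and the ryanodine receptor Ryr2 had 27.7 CPM against 0.448 CPM. The calcium pump Atp2a2 was less restricted, with 569 ± 134 CPM against 290 CPM in lymphatic endothelium (log2 2.09). Several genes called higher in muscle had a higher mean in another class. Ano1 (ENSMUSG00000031075, chromosome 7, 144588549 to 144751974) had 124 CPM in muscle and 198 CPM in epithelium, and Cav1 had 406 CPM in muscle and 1144 CPM in blood endothelium. The inositol trisphosphate receptor Itpr2 was lower in muscle (7.45 CPM, log2 -2.54), as were Orai1 (12.1 CPM, log2 -1.99) and P2rx4 (11.7 CPM, log2 -1.47). Itpr3 was also among the genes called lower and was at 0 CPM in all 5 muscle sums, so its fold is no measure. Gja1 (17.4 CPM in muscle, 462 CPM in lymphatic endothelium), Piezo1 (14.1 and 208 CPM), Trpm7 and Kcnq1 (0 CPM in muscle) were not past the threshold. With the sums thinned to 1 depth, 4 genes were called higher.

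**Figure D2:**
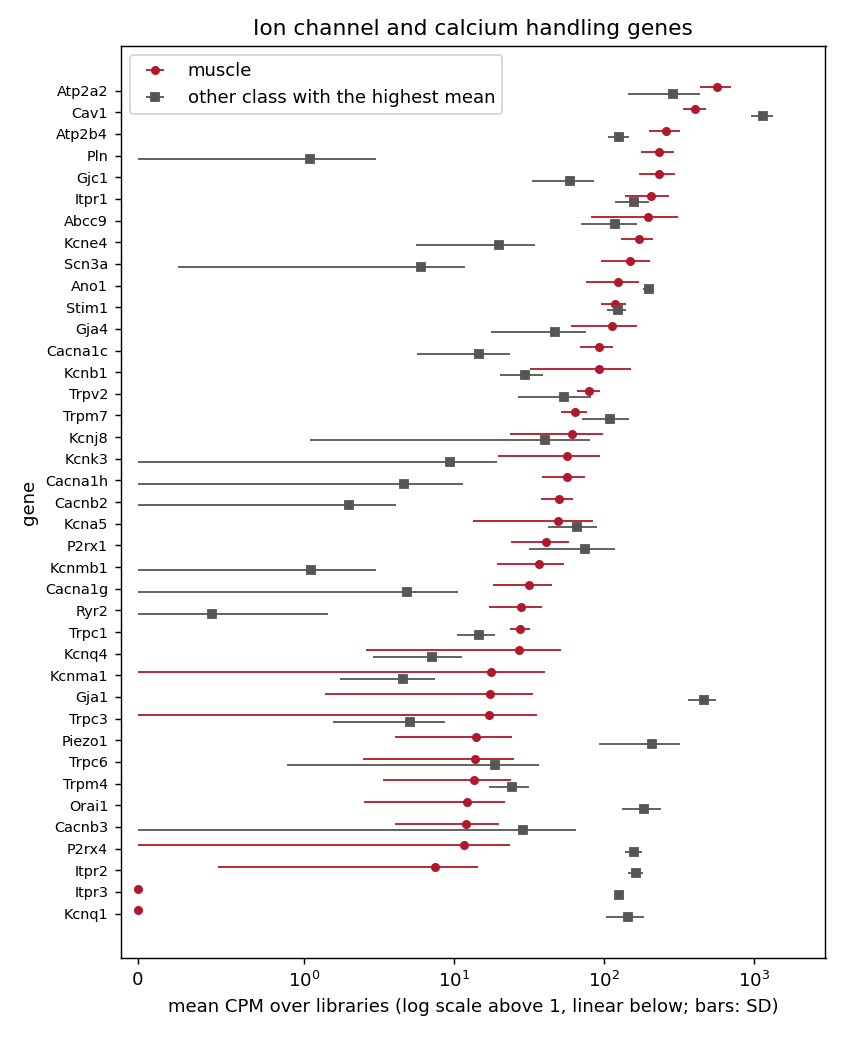
Ion channel and calcium handling genes in muscle (mean CPM ± SD of 5 libraries) and in the other class with the highest mean, on an axis that is linear near 0 and logarithmic above. Pln stands at 234 CPM in muscle and 1.10 CPM in the next class, whereas Cav1 stands at 406 CPM in muscle and 1144 CPM in blood endothelium.

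Aged against young muscle asks which muscle genes differ at 18 months. The contractile apparatus, the actin, myosin and their regulators that shorten the cell, was past the threshold in neither direction. Fibrillar collagens (Col1a1, Col3a1, Col1a2), which fibroblasts make in bulk, were lower in the aged sum. The interferon-induced genes Ifi27l2a and Iigp1, the MHC class I light chain B2m and the sulfonylurea receptor Abcc9, a subunit of the ATP-sensitive potassium channel, were lower as well. The nucleotide kinase Nme2 and the neutrophil chemokine Cxcl2 were higher. The only aged library with enough muscle cells was the male one, with 33 cells, so the aged side is a single sample.

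By edgeR, 37 of 2641 genes passed in aged against young muscle, 10 higher and 27 lower, and 198 had an unadjusted p under 0.05. DESeq2 called 7, and 1 was left with the sex labels of the middle-aged pair exchanged in the covariate. In the 3 comparisons added after the data were seen (beyond fibroblasts, beyond macrophages, and without cells rich in fibroblast markers) 0 of the 37 passed each time, and B2m and Rgs16 passed in 2. Nme2 (ENSMUSG00000020857, chromosome 11, 93949814 to 93956259) had a log2 change of 6.87 ± 1.33 (SE), with 0 UMIs in young male, 1 UMI in young female (18.0 CPM, interval 0.455 to 100.2) and 14 UMIs in aged male (134 CPM, interval 73.0 to 224). With so few UMIs in the young sums the size of this fold is no measure. Cxcl2 rose by a log2 of 2.82 ± 0.60, Grcc10 by 3.94, Nop56 by 2.60 and Rpl36al by 2.39. Nme2 rose from 8.67 and 16.8 CPM in young male and female fibroblasts to 164 CPM in those of aged male, and stood at 7.64 CPM in aged female fibroblasts. Beyond the change of fibroblasts of the same libraries its muscle change was 2.35, and Cxcl2 and Rpl36al stood at -0.38 and -0.44, all not past the threshold.

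Among the genes lower in aged muscle, Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) had a log2 change of -5.17 ± 0.75 (SE, adjusted p = 1.5e-08). Its counts were 3071, 467 (interval 305 to 685), 106, 14.3 and 95.4 CPM in young male, young female, labelled middle-aged male, labelled middle-aged female and aged male. Col3a1 (chromosome 1, 45311538 to 45349706) fell by 4.68 and Col1a2 by 4.56 on the log2 scale. Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680) fell by 5.66 ± 1.00 (adjusted p = 6.3e-06), with 79 and 12 UMIs in the young sums and 1 UMI in aged male (9.54 CPM, interval 0.242 to 53.1). Abcc9 (ENSMUSG00000030249, chromosome 6, 142587862 to 142702315) fell by 2.89 ± 0.77 (adjusted p = 0.0175) and B2m by 3.36, while Iigp1, Rgs16 and Serpinf1 passed with 3 UMIs or fewer in aged male. The fibroblast markers are a measured limit here. In young male muscle 21 of 86 cells, and in young female 5 of 23, held at least as many fibroblast as smooth muscle marker UMIs, against 4 of 33 in aged male. With such cells left out, Col1a1 stood at -1.82 and was not past the threshold, while Col3a1 at -3.46, Col1a2 at -2.85, Col6a1 at -3.63 and Abcc9 at -3.87 passed. Ifi27l2a stood at -3.75 and lost its call. Beyond the change of fibroblasts Ifi27l2a stood at -5.25 and passed, and Abcc9 at -0.90, Col1a1 at -1.70, Col3a1 at -0.73 and Col1a2 at -1.99 did not. Xist and the noncoding RNA Gm42418 were also among the genes called lower. Xist was at 0 UMIs in both young and aged male muscle and at 68 in young female, so its call is no measure of age.

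By list in muscle, none of 30 contractile, 8 smooth muscle marker, 54 oxidative phosphorylation, 9 endothelial junction, 3 lymphatic identity, 5 resident macrophage or 4 cell cycle genes passed. Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590) stood at -0.25, Myh11 at 0.44, Tagln at 0.47, Cnn1 at -0.51 and Des at -0.21. The contractile list made up 43641 and 43528 CPM of the young and 55283 CPM of the aged male sum. Collagens had 6 of 27 lower (16 adjusted over the list alone), and fibroblast markers 6 of 9 (7 alone), among them Dcn and Gsn. The interferon list had 2 of 9 lower, MHC class I 1 of 4 (B2m), channels 1 of 18 (Abcc9), antioxidant genes 1 of 19 (Gpx3), and each count held over the list alone. Inflammatory genes had 1 of 19 higher (2 higher and 1 lower alone), senescence genes 1 of 14 lower (1 higher and 1 lower alone), and dissociation genes 1 of 35 higher (Hspa1b) and 1 lower (Socs3). Complement (9 genes) and macrophage markers (3 genes) had none past over all genes, with 4 and 2 lower over the list alone. Camera called collagens (median log2 -2.02, adjusted p = 1.0e-17), fibroblast markers (-2.75, or -2.57 with a member at 0 in aged male set to 3 counts, 5.2e-15), complement (-1.08, 0.0013) and macrophage markers (-3.997, 0.0035), each with adjusted p = 0.927 with an estimated correlation, and fry called 0 of 18 lists. The contractile list had a median of 0.21, a mean of -0.04 and an upward test, and the antioxidant, junction and lymphatic identity lists also differed in sign between median, mean and test.

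**Figure D3:**
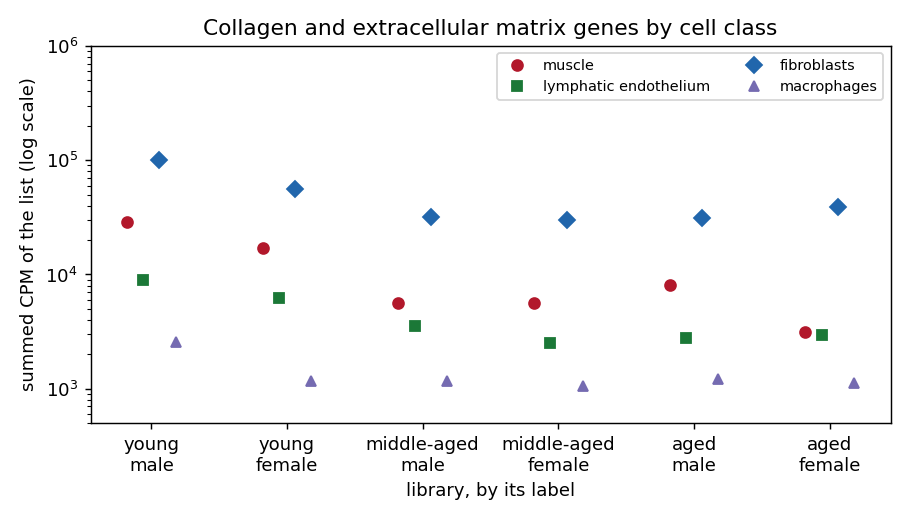
Summed CPM of the collagen and matrix list per library in muscle, lymphatic endothelium, fibroblasts and macrophages (log axis), including the aged female sums of 3 muscle and 4 lymphatic endothelial cells. The young male library has the highest value in each class, 99968 CPM in fibroblasts and 29071 CPM in muscle.

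Lymphatic endothelium lines the vessel. Aged against young, the gene for P-selectin (Selp), the adhesion molecule that lets leukocytes roll, was higher, and so were the granulocyte growth factor Csf3, the chemokines Ccl2 and Cxcl2 and the heme-degrading enzyme Hmox1. The flow-induced factor Klf2 and the tight junction gene Cldn5 were lower. Genes of fibroblasts (Col1a1, Col3a1) and macrophages (Lyz2) were lower too. The identity genes Prox1 and Flt4 were not past the threshold. Again the aged side is aged male alone, with 96 cells against 25 and 23 in the young libraries.

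In lymphatic endothelium edgeR called 219 of 3261 genes, 128 higher and 91 lower, with 668 at an unadjusted p under 0.05, and DESeq2 called 30. Selp (ENSMUSG00000026580, chromosome 1, 164115264 to 164150026) had a log2 change of 6.70 ± 0.94 (SE, adjusted p = 3.6e-10), with 1 and 3 UMIs in young male and female (7.45 CPM, interval 0.189 to 41.5, and 22.6 CPM, interval 4.67 to 66.2), 0 in labelled middle-aged male, 161 in labelled middle-aged female and 141 in aged male (180 CPM, interval 152 to 212). Csf3 (ENSMUSG00000038067, chromosome 11, 98701263 to 98703629) had a log2 change of 6.61 ± 0.67 (adjusted p = 1.1e-19), with 4, 1, 4, 562 and 564 UMIs in the same order. Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589) rose by a log2 of 4.51 ± 0.52 (adjusted p = 3.3e-15), Nme2 by 4.48, Cxcl2 by 3.47, Ccl2 by 3.36, Txnrd1 by 3.29, Hspa1b by 3.13 and Gdf15 by 1.89. Beyond the change of fibroblasts Nme2, Cxcl2 and Gdf15 turned to -0.28, -0.0711 and -0.22, and Hmox1 at 1.50, Ccl2 at 1.27, Txnrd1 at 2.06 and Hspa1b at 1.91 did not pass, while Selp at 7.67 did. Fosl1 had 0 and 2 UMIs in the young sums (for 2 UMIs 15.1 CPM, interval 1.83 to 54.5) and 180 in aged male. The sizes of these fitted folds also take in a labelled sex effect, which the middle-aged pair with its contradicted labels helps set. In young and aged male Selp had 7.40 and 203 normalised CPM and Csf3 29.6 and 811. Both are smaller ratios than the fitted ones. Col1a1 had a log2 change of -7.13 ± 0.72 (adjusted p = 1.7e-19), Lpl one of -5.93 and Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321) one of -5.65 ± 0.63 (adjusted p = 2.8e-16). Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656) fell by 2.97 ± 0.39 (adjusted p = 1.9e-11), C3 by 3.78 and Cldn5 by 1.60. Spp1, also called lower, had 49 UMIs (365 CPM) in young male and 0 in the other libraries, so its fold is no measure. Prox1 stood at 0.37, Flt4 at -0.41, Lyve1 at -2.55 and Ccl21a at 0.77, all not past the threshold. Beyond the change of fibroblasts Prox1 turned to -2.43 and passed. Ccl21a had 0 and 882 normalised CPM in young male and female and 34.5 in aged male, and with sex left out of the model it turned to -3.81 and passed. Of the 219 genes, 7 passed in the same direction in each of the same 3 added comparisons: Csf3, Lyz2, Lpl, Nolc1, Hspa1a, Tppp3 and Noct.

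By list in lymphatic endothelium, inflammatory genes had 5 of 16 higher (6 higher and 1 lower adjusted over the list alone), antioxidant genes 3 of 18 higher (5 higher and 1 lower alone) and senescence genes 3 of 15 higher and 2 lower (4 and 3 alone). The inflammatory list made up 5073 and 4144 CPM in young male and female and 6744 CPM in aged male. The antioxidant list made up 3888, 4703 and 7120 CPM in the same order. The aged female sum of 4 cells, which was not fitted, had 3996 CPM (67 UMIs) and 3698 CPM (62 UMIs) of these lists. So few cells cannot settle whether both aged libraries share the rise. Dissociation and immediate early genes went both ways, 5 of 34 higher and 6 lower (8 and 9 alone). Junction genes had 2 of 25 higher and 2 lower (2 and 3 alone). Collagens had 7 of 28 lower (8 alone), fibroblast markers 3 of 7, macrophage markers 1 of 9 (2 alone), resident macrophage genes 2 of 8 (Igfbp4, and Retnla, which turned from -3.74 to 3.81 and passed as higher with the labels of the middle-aged pair exchanged, and to 5.04, not past the threshold, with free RNA subtracted), oxidative phosphorylation 2 of 50 (Ndufb9, Atp5o), and the contractile (14), interferon (10), complement (10) and endothelium marker (8) lists 1 each (Pdlim3, Ifi27l2a, C3, Cldn5). None of 15 lymphatic identity, 12 MHC class I, 4 MHC class II, 8 channel or 5 cell cycle genes passed over all genes, with 2 higher over the list alone in each of the last 3. Camera called collagens (median log2 -1.46, adjusted p = 6.1e-08), macrophage markers (-5.41, or -5.04 with a member at 0 in aged male set to 3 counts, 6.1e-08), fibroblast markers (-2.94, 1.7e-05) and complement (-1.64, 5.8e-04), each with adjusted p = 0.756 with an estimated correlation, and fry called 0 of 19. The senescence and cell cycle lists differed in sign between median, mean and test.

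Fibroblasts were compared in all 6 libraries. Genes with small p values for aged against young included the orphan receptor Mrgprg and the Wnt regulator Dact2, which stood higher, and the lipid carrier Fabp4 and Nrep, which stood lower. None passed. The collagen Col1a1 was highest in young male fibroblasts, followed by those of young female. Markers of macrophages and endothelium inside the fibroblast sums were called lower as groups by camera with its fixed correlation, but not with an estimated one or by fry, and no member passed over all genes.

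For fibroblasts edgeR called 0 of 11838 genes, with 415 at an unadjusted p under 0.05, and DESeq2 called 29. Mrgprg (ENSMUSG00000050276, chromosome 7, 143763710 to 143766993) stood at a log2 of 5.68, with 0.952, 3.28, 147, 56.8, 127 and 90.9 normalised CPM in young male, young female, labelled middle-aged male, labelled middle-aged female, aged male and aged female. Col1a1 stood at -2.41, with 14026, 3221, 1339, 1183, 1115 and 1609 normalised CPM. Without the middle-aged pair, a choice made after seeing the data, 54 genes passed, 17 higher and 37 lower. These included Mrgprg (5.82 ± 0.54, SE, adjusted p = 0.0033), the epidermal gene Dmkn (3.55), the integrin Itgb7 (2.92) and Dact2 (2.13). Those that fell included thrombospondin 4 (Thbs4, ENSMUSG00000021702, chromosome 13, 92751590 to 92794818) at -5.91 ± 0.50 (adjusted p = 0.0033), Col8a1 at -4.63, Ptn at -4.56, Itm2a at -3.10, Thbs1 at -2.93, Fabp4 at -2.89 and the adhesion gene Vcam1 at -1.81. The count was 115 without labelled middle-aged male, 121 without labelled middle-aged female, 3 without young female and 0 without each of the others.

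Lists in fibroblasts had no member past the threshold over all genes. Over the list alone 2 senescence genes (of 24) and 1 gene each in the lymphatic identity, endothelium and adipocyte marker lists passed, all lower. Camera called 9 of 25 lists, all downward: collagens (42 genes, median log2 -1.07, adjusted p = 5.6e-10, and 0.667 with an estimated correlation), macrophage markers (12, -1.96, 6.2e-10), resident macrophage genes (16, -1.36, 7.2e-08), endothelium markers (5, -2.35, 2.1e-05), lymphatic identity (9, -0.62, 0.0151), contractile apparatus (22, -0.36, 0.0089), smooth muscle markers (5, -0.96, 0.0331), MHC class II (6, -1.28, 0.0491) and adipocyte markers (6, -1.57, 0.04999). With an estimated correlation these had adjusted p = 0.627 for the macrophage, resident macrophage, endothelium and lymphatic identity lists, 0.743 for contractile, 0.674 for smooth muscle and 0.816 for the MHC class II and adipocyte lists, and fry called 0. Not called were channels (26 genes), inflammatory (36), interferon (30), MHC class I (15), senescence (24), dissociation (35), oxidative phosphorylation (55), antioxidant (28), complement (16), junctions (19), cell cycle (14) and the markers of fibroblasts (12), lymphocytes (4), erythrocytes (4), skeletal muscle (6) and epithelium (4). The oxidative phosphorylation, senescence, antioxidant, complement and junction lists differed in sign between median, mean and test.

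In macrophages the gelatinase Mmp9, the selenoprotein Selenom and the microtubule ligase Mid1 had the smallest p values among genes that stood higher in aged against young, and the collagens Col1a1 and Col3a1, which macrophages hardly make, and the prothrombinase Fgl2 had the smallest among those that stood lower. None of these passed. The scavenger receptor Cd163, the hyaluronan receptor Lyve1, the MHC class II gene H2-Aa and the cytokine Il1b did not pass either.

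For macrophages edgeR called 0 of 9319 genes, with 299 at an unadjusted p under 0.05, and DESeq2 called 5. Col1a1 stood at -4.39, with 229, 31.0, 6.72, 7.33, 8.37 and 2.30 normalised CPM in the order of the fibroblast values, Fgl2 at -2.15, Mmp9 (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850) at 1.65, Cd163 at 0.51, Lyve1 at 0.55, H2-Aa at 0.47 and Il1b at -0.08. Without the middle-aged pair 65 genes passed, 30 higher and 35 lower. Those that rose included the interferon-induced Ifit1 (1.73 ± 0.30, SE, adjusted p = 9.7e-05), Mmp9 (1.64), Il6 (1.62), Kitl (1.40) and the transferrin receptor Tfrc (1.23), and those that fell Col1a1 (-4.51), Col3a1 (-3.64), the sodium pump subunit Atp1b1 (-2.50), the complement gene C2 (-2.54) and Fgl2 (-2.15). Leaving out 1 library gave 95 without labelled middle-aged male, 96 without labelled middle-aged female, 89 without aged female, 14 without aged male, 5 without young female and 0 without young male.

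No list in macrophages had a member past the threshold over all genes. Over the list alone 15 of 27 collagens, 7 of 12 fibroblast markers and 1 each of 16 complement, 6 lymphatic identity and 8 skeletal muscle marker genes were lower. Camera called 6 of 23 lists. These were collagens (median log2 -1.80, adjusted p = 7.6e-27, and 0.395 with an estimated correlation), fibroblast markers (-1.40, 6.6e-17, and 0.326), skeletal muscle markers (-1.52, 1.8e-04, and 0.722), senescence (-0.26, 0.0035, and 0.710), MHC class I (-0.30, 0.0232, and 0.819) and, upward, adipocyte markers (0.92, 0.0050, and 0.722). Fry called 0. The other 17 lists, among them inflammatory, interferon, MHC class II, resident macrophage and macrophage marker genes, were not called. Inflammatory, junction and lymphatic identity lists differed in sign between median, mean and test.

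Middle-aged against young muscle had both libraries of each age. The transcription factor Runx1, the co-chaperone Dnajb9 and the metal-binding Mt2 were higher, and fibroblast genes such as Clec3b, Dcn and the collagens and the complement gene C3 were lower. The contractile genes Acta2, Myh11, Tagln, Cnn1 and Des were not past the threshold. In this contrast 59 of 2641 genes passed, 15 higher and 44 lower, with 264 at an unadjusted p under 0.05, and DESeq2 called 11. Mid1 (ENSMUSG00000035299, chromosome X, 169685199 to 170005736) rose by a log2 of 3.09, Cox17 by 2.34, Runx1 by 2.21 and Dnajb9 by 2.01. Beyond fibroblasts of the same libraries these 4 stood at 1.01, 1.54, 0.93 and 1.53, and Mt2 at 0.46. Beyond macrophages they stood at 0.47, 1.44, 1.37 and 1.15, and Mt2 at 0.0614. None of these values passed. With cells rich in fibroblast markers left out, Mid1 at 3.29 and Mt2 at 1.61 passed, and the others did not. For these genes a rise of muscle and one shared with other classes cannot be told apart. Col1a1 had a log2 change of -4.95 ± 0.58 (SE, adjusted p = 3.1e-14), Dcn one of -4.52 and Gpx3 (ENSMUSG00000018339, chromosome 11, 54902453 to 54910377) one of -3.01. Clec3b had 127 and 18 UMIs and C3 118 and 8 in the young sums, and each had 0 and 2 in the middle-aged ones (for 2 UMIs 9.54 CPM, interval 1.16 to 34.5). Ifi205, also called lower, had 23 and 4 UMIs in the young and 0 in both middle-aged sums. Collagens had 17 of 27 lower (20 adjusted over the list alone) and fibroblast markers 8 of 9 (9 alone). Camera called both (adjusted p = 5.3e-25 and 4.5e-20) and the dissociation, complement and macrophage marker lists (0.0217, 0.0443 and 0.0443), each at 0.851 with an estimated correlation. Fibroblast-rich muscle cells were 24.4% and 21.7% in the young and 4.08% and 3.03% in the middle-aged sums. Without them Col1a1 stood at -2.28 and passed and Dcn at -1.56 and did not, and beyond macrophages Col1a1 stood at -0.74 and did not pass, while Dcn at -3.66 did. Gpx3 alone passed in each of the same 3 added comparisons.

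Aged against middle-aged muscle gave 3 calls by edgeR, with 83 genes at an unadjusted p under 0.05, and 0 by DESeq2. The protease Pappa2 (ENSMUSG00000073530, chromosome 1, 158711727 to 158980490), which cleaves a carrier of insulin-like growth factor, was higher at a log2 of 8.86 ± 1.84 (SE, adjusted p = 0.0014). It had 0 and 2 UMIs in the labelled middle-aged male and female sums (at most 48.8 CPM, and 9.54 CPM, interval 1.16 to 34.5), 19 UMIs in aged male (181 CPM, interval 109 to 283), and 1 and 10 UMIs in young male and female. The size of the Pappa2 fold rests on a sum at 0 and on the contradicted sex labels, so it is no measure. The calcification inhibitor Mgp (ENSMUSG00000030218, chromosome 6, 136872435 to 136875823) was higher at 2.75 ± 0.54 (adjusted p = 4.7e-04), with 529 and 153 CPM in the middle-aged sums, 1765 CPM in aged male, and 159 and 3128 CPM in young male and female. The third call was Xist, at 0 UMIs in aged male and in the library labelled middle-aged female and 98 in the library labelled middle-aged male, so this call is no measure of age either.

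The sex comparison in each class mixes labels that Xist contradicts. With all libraries and labels as given, no fibroblast, macrophage or lymphatic endothelial gene passed, and 4 genes passed in muscle, among them Col1a1 and the lipoprotein gene Apoe. Without the middle-aged pair, fibroblasts differed in the estrogen sulfotransferase Sult1e1, the complement gene C7 and the protease inhibitor Serpine2, which were lower in female, and in the cadherin Cdh11 and the secretogranin Scg3, which were higher. Macrophages of the female libraries had more of the secretory gene Mucl1 and the acute phase gene Saa3.

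Labelled female against male, edgeR called 0 of 11343 genes in fibroblasts (91 at an unadjusted p under 0.05; DESeq2 1), 0 of 8829 in macrophages (148; DESeq2 2) and 0 of 2539 in lymphatic endothelium (82; DESeq2 0). In muscle it called 4 of 1955 (85; DESeq2 1), all lower in labelled female: Col1a1 (-2.84), H2-M9 (-2.82), Col1a2 (-2.15) and Apoe (-2.01). The count was 0 with no count filter, with age left out and with at least 200 genes and at most 20% mitochondrial UMIs, and 16 with doublets kept. In this muscle fit Xist stood at -0.0615 and Ddx3y at 0.62, neither past the threshold. All 4 genes were lower in the library labelled middle-aged female, which has the Y-linked counts, than in the one labelled middle-aged male. Col1a1 had 17.1 and 100 normalised CPM there. These calls are therefore no measure of sex. Fibroblast and macrophage markers in the muscle sums were at 15519 and 795 CPM in young male against 4351 and 162 CPM in young female. Genes of smallest p that did not pass included AC160336.1 in fibroblasts (1.69) and macrophages (1.92), Nr4a2 in fibroblasts (-1.44), Neat1 in lymphatic endothelium (-1.41) and Cd200 in muscle (1.86). Without the middle-aged pair, added after seeing the data, 185 fibroblast genes passed, 111 higher and 74 lower, and 63 macrophage genes, 29 higher and 34 lower. Sult1e1 (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594) had a log2 difference of -9.81 ± 0.54 (SE, adjusted p = 3.6e-05), with 392 and 384 normalised CPM in young and aged male, 0.263 and 0.736 in young and aged female, 0 in labelled middle-aged male and 619 in labelled middle-aged female. C7 (ENSMUSG00000079105, chromosome 15, 4988762 to 5063740) stood at -6.21, Ramp1 at -4.99, Serpine2 at -4.08, Cdh11 at 5.74 and Scg3 at 4.94. Xist and Ddx3y passed as well, Ddx3y at 0 in both female libraries. In macrophages Mucl1 was at 0.405 and 0 normalised CPM in young and aged male and 11.8 and 166 in young and aged female, Saa3 at 1.22, 0, 13.5 and 137 in the same order, and Lyz1 stood at a log2 of 1.63, Cxcl10 at -1.90 and Cxcl1 at -1.78. In aged female Mucl1 and Saa3 had 188 and 155 CPM in macrophages, without normalisation factors, against 3.89 and 43.5 CPM in free RNA and 0.176 and 4.04 CPM in epithelium. In young female they had 12.6 and 14.3 CPM in macrophages against 1.34 and 20.1 CPM in free RNA, so Saa3 was lower in macrophages there. Free RNA alone would need a share of 71.5% to give that Saa3 count, while Csn3 allowed 1.23%. Fibroblasts gave 181 calls without labelled middle-aged male alone and 217 without labelled middle-aged female alone. For macrophages these were 71 and 90, with 3 without each aged library.

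Shares of 15 cell classes, the unnamed one included, were compared between aged and young as cell numbers. Neutrophils, the first leukocytes into injured tissue, stood higher, at 2.59% in aged male and 2.20% in aged female against 0.0882% and 0.0902% in young male and female, and at 0.226% and 14.4% in labelled middle-aged male and female. EdgeR called 0 classes, with 0 at an unadjusted p under 0.05, and no other tool was run. The neutrophil log2 change was 4.77 ± 2.13 (SE, adjusted p = 0.953, higher in both aged libraries). Lymphatic endothelium made up 0.315%, 0.519%, 0.340%, 9.12%, 3.28% and 0.283% of the cells (log2 2.44), and muscle 1.08%, 0.519%, 0.792%, 3.31%, 1.13% and 0.213% (log2 -0.32), with exact intervals of 0.776% to 1.58% in aged male and 0.0439% to 0.620% in aged female muscle.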

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

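All tests in this part were chosen after the results they measure had been seen, apart from the comparison of shares and the count over splits of the libraries.

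The first pattern is the sex labels of the middle-aged pair. Xist in the library labelled middle-aged male was at 125% of the mean of the young and aged female libraries, and Y-linked counts in the library labelled middle-aged female were at 124% of the mean of the young and aged male ones. A mixture of cells of both sexes in each would need Xist and Y-linked counts together, and the lower of the pair was at most 0.0516% of the level of the other libraries, which excludes it. Both libraries (2) went against their labels in opposite directions, which is what an exchange of labels within the pair needs. It may have happened on the label or at any earlier step, which the counts cannot show, and an exchange with samples from outside the series was not tested.

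The second pattern is the collagens and fibroblast markers that were lower in the aged than in the young sums of muscle and lymphatic endothelium. Free RNA of the suspension is excluded as the whole source in muscle, but not as a part of it. The macrophage markers allowed a share of 10.7% free RNA in young male and 1.98% in young female, the latter from 9 UMIs. The share that the fibroblast markers needed was 6.90 times the share allowed in young male (5.97 times the highest share allowed) and 21.9 times in young female (11.6). In lymphatic endothelium this ratio was 1.06 in young male and 3.48 in young female (2.79 over the highest share allowed). Free RNA as the whole source therefore stays open there for the young male sum. With free RNA subtracted, where its share in young male was itself taken from the fibroblast markers, Col1a1 went from -7.13 to -5.35 and Col3a1 from -5.79 to -4.12 and both passed, while Col1a2 went from -4.82 to 1.40 and did not. Whole fibroblasts mixed into the class could explain part of the pattern, since decorin (Dcn) and Col1a1 needed similar fibroblast shares (ratios of 0.813, interval 0.685 to 0.964, and 0.810, interval 0.427 to 1.58, in young male and female muscle, and 1.24, interval 0.785 to 1.95, and 0.964, interval 0.575 to 1.65, in lymphatic endothelium). Over all fibroblast markers the shares needed ranged wider, from 6.83% to 25.0% and from 0% to 13.2% in muscle and from 2.63% to 17.8% and from 1.11% to 7.87% in lymphatic endothelium, with 6 UMIs or fewer behind each end apart from the highest in both muscle sums and in young female lymphatic endothelium. Without the cells rich in fibroblast markers, a selection that itself removes cells with collagen, the muscle value of Col1a1 went from -5.17 ± 0.75 (SE) to -1.82 ± 0.75 and no longer passed because the fold fell. Col3a1 went from -4.68 ± 0.69 to -3.46 ± 0.76 and Col1a2 from -4.56 ± 0.69 to -2.85 ± 0.73, both still past the threshold, and Dcn from -2.75 ± 0.65 to -2.74 ± 0.82, not past it. The cells left out are therefore not the whole cause in muscle. Beyond the change of fibroblasts of the same libraries Col1a1 stood at -1.70 ± 0.80, Col3a1 at -0.73 ± 0.80 and Col1a2 at -1.99 ± 0.79, none past the threshold because the folds fell, and Dcn at -2.78 ± 0.80 and passed. Fibroblast RNA in the cells kept stays open. A difference of age stays open and untested in both classes, with 1 aged library.

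The third pattern is the genes called higher in the aged sums of the same classes. In muscle these genes moved by a median log2 of 1.99 (bootstrap interval 1.15 to 2.86) in fibroblasts and macrophages of the aged male library as well, against 2.37 in muscle, so a difference of that whole library and a difference of the muscle cannot be told apart. In fibroblasts and macrophages of aged female the same genes stood at a median of -0.42, so their rise in these classes was not shared by both aged libraries. In lymphatic endothelium the same median was 0.55 (interval 0.43 to 0.64) against 1.71 in the class itself. Its genes were chosen for their rise in that same sum, which raises the value in the class alone. The 2 medians therefore cannot exclude a difference of the whole library. In both other classes 16 of these genes moved by a log2 of at least 1. The median in aged female fibroblasts and macrophages was -0.02. Only 1 aged library had enough cells of either class, so age and the single aged male library cannot be told apart.

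The count of sex calls was compared with other divisions of the libraries into 3 and 3. With 10 splits no share under 0.05 can be had. The labelled split gave 0 calls in fibroblasts and 0 in macrophages, and the highest other gave 381 and 16. That split, young male, labelled middle-aged female and aged male against the rest, puts the libraries with Y-linked counts on 1 side and so points to a structure of the samples.

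Shares of 4 classes moved in opposite directions in the male and the female libraries from young to aged with exact intervals of young and aged apart in both sexes, a difference that was not tested, with 1 library per age and sex. B cells rose from 0.0756% to 1.81% in male and fell from 9.11% to 2.13% in female libraries, a difference of log2 changes of 6.68. T cells differed by 4.36, from 0.239% to 1.36% in male and from 7.94% to 2.20% in female. Fibroblasts differed by 0.774 on the log2 scale, from 41.4% to 49.0% in male and from 41.5% to 28.8% in female. Monocytes differed by -4.56, from 6.65% to 0.989% in male and from 1.53% to 5.39% in female. Lymphatic endothelium, muscle and the unnamed clusters also moved in opposite directions, with intervals that overlap in at least 1 sex.

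Epithelial cells, whose genes were not compared by age or sex, were found in 3 libraries, with 97 cells in young female (2.19%, exact interval 1.78% to 2.66%), 325 in labelled middle-aged male (5.25%, 4.71% to 5.84%) and 219 in aged female (15.5%, 13.7% to 17.5%). The other 3 libraries had 0, which allows up to 0.0378% in young male, 0.301% in labelled middle-aged female and 0.102% in aged male.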

How the results depend on the processing

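The alternatives with the middle-aged pair left out or its labels exchanged, with sums of any cell number, with the change taken beyond fibroblasts or macrophages, and with fibroblast-rich cells left out were chosen after seeing the data, and the others were planned. Over 200 alternative counts 126 stayed within 1.5 times the reported count and 74 did not. Of 9955 values of named genes under alternatives, 9130 stayed on their side of the threshold. Another 329 kept direction and no longer passed, and 479 kept direction and newly passed. The other 17 changed sign with the reported or the alternative value past the threshold. Changes of sign with neither value past it are counted in the 9130. Where no reason is given, the cause was not tested.

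With DESeq2 the calls were 7 for aged against young muscle, 30 for lymphatic endothelium, 29 for fibroblasts and 5 for macrophages, 11 and 0 for middle-aged against young and aged against middle-aged muscle, and 1, 1 and 2 for sex in muscle, fibroblasts and macrophages. With no count filter, which tests more genes, they were 7 in muscle, 3 in fibroblasts, 55 in macrophages and 18 for middle-aged against young, and for sex 0 in muscle, 16 in lymphatic endothelium and 20 in macrophages. With sex left out they were 13 for aged against young and 1 for aged against middle-aged muscle, and with age left out 0 for sex in muscle. With at least 200 genes and at most 20% mitochondrial UMIs they were 21, 1 and 0 in muscle (aged against young, aged against middle-aged, sex) and 2 for sex in lymphatic endothelium. With doublets kept they were 6 for aged macrophages, 16 for sex in muscle and 4 for sex in macrophages, and with free RNA subtracted 2 for sex in muscle and 2 in lymphatic endothelium.

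With the labels of the middle-aged pair exchanged, aged against young gave 1 call in muscle, 42 in fibroblasts and 12 in macrophages, and aged against middle-aged muscle 1. With the pair left out it gave 54 in fibroblasts and 65 in macrophages, and sex gave 185 and 63. With at least 1 cell per library it gave 9 in muscle and 11 in lymphatic endothelium, middle-aged against young 17 and aged against middle-aged 0. The sums of 3 and 4 cells leave fewer genes to test and also add the aged female library to the aged side. Which of these lowered the counts was not tested. Beyond fibroblasts lymphatic endothelium gave 69 calls, of which 27 were shared with the reported ones. Beyond macrophages muscle gave 2 (aged) and 15 (middle-aged) and lymphatic endothelium 33. A change beyond another class may lie in either class. With fibroblast-rich cells left out muscle gave 19 calls (18 shared) for aged and 18 (16 shared) for middle-aged against young.

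Leaving out 1 library gave 0 to 121 calls for aged fibroblasts, 0 to 96 for aged macrophages, 0 to 217 for sex in fibroblasts and 0 to 90 for sex in macrophages, the highest without labelled middle-aged female each time. It gave 58 for middle-aged against young muscle, 5 for sex in muscle, 0 for sex in lymphatic endothelium, 0 to 0 for class shares, 24 to 31 for channel genes, and 6 to 10 lists in fibroblasts and 6 to 10 in macrophages. Channel genes fell to 4 calls with sums thinned to 1 depth, where fewer genes (1864) were tested at lower counts.

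Of the lists, fry and camera with an estimated correlation called 0 in every class. With sex left out muscle had 2, and lymphatic endothelium had 1 with labels exchanged and 7 with free RNA subtracted.

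Signs changed, with the reported or the alternative value past the threshold, for these named genes. Beyond fibroblasts muscle values became -0.38 for Cxcl2, -0.44 for Rpl36al and 2.46 for Fabp4, and lymphatic endothelial ones -0.28 for Nme2, -0.0711 for Cxcl2, -0.22 for Gdf15, -2.43 for Prox1 and 1.17 for Pdlim3. Of these, Fabp4 and Prox1 passed with the new sign. Beyond macrophages they became -0.30 for Rpl36al in muscle and 0.16 for Pdlim3 in lymphatic endothelium. In lymphatic endothelium free RNA subtracted gave 1.40 for Col1a2 and 5.04 for Retnla, exchanged labels 3.81 for Retnla, and sex left out -3.81 for Ccl21a, which passed, as did Retnla with exchanged labels. Ly6a for sex in macrophages ran from -1.91 to 1.56 with 1 library left out, became 1.56 without either middle-aged library, and was 1.56 without both. Each of these values of 1.56 passed.

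Filters of at least 1000 genes or at most 5% mitochondrial UMIs, and most fits without 1 library, gave no value for muscle and lymphatic endothelium, where too few sums of 20 cells were left. The labels give no replicate numbers; labelled sex, which the model of the age comparisons holds, is what links libraries across ages. In muscle a count of 0 allowed up to 15.8 CPM in young male, 35.2 CPM in aged male and 48.8 CPM in labelled middle-aged male.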

Other observations

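Genes of the mammary gland were higher in 3 of the libraries than in the others, apart from Csn2 in young female. The milk protein genes Csn2 and Csn3, the casein genes of the mammary gland, reached 2298 and 1547 CPM of all cells in aged female and 223 and 353 CPM in the library labelled middle-aged male, while young female had 0 and 33.3 CPM. The prolactin receptor gene Prlr stood at 371 CPM in young female, 160 CPM in labelled middle-aged male and 221 CPM in aged female, and at 1.46, 0.893 and 0.714 CPM in young male, labelled middle-aged female and aged male. The libraries with these genes are those with Xist. The muscle class of 227 cells is led by Tagln, Myh11, Tpm2 and Acta2, and a separate unnamed cluster of 303 cells with the basal keratins Krt14, Krt5 and Krt17 beside Acta2 and Cnn1 occurs only in the same 3 libraries.

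Fibroblasts formed different clusters in different libraries. A cluster with Col1a1, Col3a1 and Sparc among its leading genes held 73.6% of young male fibroblasts and at most 2.96% of those of any other library. One with the epidermal genes Dmkn and Krtdap, the chemokines Ccl2 and Cxcl1 and the prostaglandin synthase Ptgs2 held 85.1% in labelled middle-aged female and 85.6% in aged male, against 0.365% in young male, 0.217% in young female, 2.47% in labelled middle-aged male and 1.48% in aged female. One with Akr1c18 and Mrgprg held 60.8% in aged female, 23.1% in young female and 23.1% in labelled middle-aged male, and one with Scg3 and Cdh11 held 36.2% in young female, 16.1% in labelled middle-aged male and 8.87% in aged female. No batch correction was applied. These values were picked after the data had been seen, and no test was run on them.

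Resident macrophages with Cd209f, Folr2, C1qa and Lyve1 numbered 1122, 687, 824, 14, 424 and 256 from young male to aged female. Macrophages with Ccl4, Ccl3, Hmox1 and Cxcl2 numbered 46, 132, 664, 73, 124 and 20. The inflammatory gene list made up 17016, 13739, 30765, 43026, 23471 and 12843 CPM of the macrophage sums and 8292, 8623, 11585, 31636, 15796 and 6223 CPM of the fibroblast sums, highest in the library labelled middle-aged female in both. That library also had the fewest cells, the highest median depth and 14.4% neutrophils.

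The noncoding RNA Gm42418 (ENSMUSG00000098178, chromosome 17, 39846958 to 39848788) took 86283 and 13100 CPM of young male and female fibroblasts, 2218 and 3541 CPM of the labelled middle-aged male and female ones, and 3803 and 49918 CPM of those of aged male and female.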
